A study of Mus musculus with 11 samples.

How the data were processed

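The series profiles C2C12 cells, a mouse myoblast line that proliferates in rich medium and fuses into multinucleate myotubes when serum is withdrawn. There are 11 samples in 11 groups, with 1 sample in each. ChIP-seq of the muscle transcription factors MyoD and MyoG and of the enhancer-associated histone mark H3K4me1 makes up 5 samples. PolyA RNA-seq makes up 4 samples, taken 4 h after the switch to differentiation medium with 2% horse serum. The remaining 2 samples, ribosome-depleted RNA of myotubes and of satellite cells, were not analysed here. Proliferating myoblasts were kept in 10% fetal bovine serum, and myotubes were taken at 48 h of differentiation, per the labels. Groups were taken from the labels alone.

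The authors' expression values come as 2 tables, 1 per experiment, each with an FPKM per coding sequence and condition (fragments per kilobase, scaled to the mapped fragments of the library) for 24333 coding sequences under 20368 gene symbols, per the file headers. The tables have the layout of a Cuffdiff comparison of coding sequences, but no header names the tool, its version or its scaling. TopHat and the mm9 build are named in the submitters' processing notes, without versions. Each table was normalized on its own, so levels are tested only within a table. The deposited p-value and q-value of each coding sequence are the authors' own. A q-value under 0.05 is the authors' threshold of significance in each table. The p-values were also adjusted anew over gene lists and turned into standard errors, which are not the authors' results. The labels tie each table to exactly 2 samples. The condition named for GFP in a table was taken as the GFP control, and the other, which the tables call by another name than the labels do, as the DRRi or the pHAN_DRR1.2 library. Read depths of the RNA libraries were not given in the sources used here.

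MyoD and MyoG peaks were called with MACS, per the file headers, and carry a peak score given by the authors of at least 60; its definition, the MACS version, the control and the threshold were not given in the sources used here. Many of the highest scores sit at a ceiling from 3100 upward, so ranks among them carry little. Scores are used only within a list. The labels name 2 runs for each MyoD or MyoG sample and the files hold 1 list each; whether runs were pooled before peak calling was not given in the sources used here, and the header of the MyoD myotube list names run 2. H3K4me1 domains are on windows of 200 bp, and SICER is named in the submitters' processing notes. Each domain carries a deposited count of ChIP reads, a count of control reads and their fold, per the column layout; where control reads are present, the deposited fold equals the ratio of the counts times 1 constant per file (0.858 in myoblasts, where 4 domains have 0 control reads, and 0.983 in myotubes). The domains hold 9555012 ChIP reads in myoblasts and 8842751 in myotubes. Those sums cover reads inside domains and are not library depths.

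Expression was computed per gene symbol as the sum of the FPKM of its coding sequences. Genes with a mean of both conditions of 1 FPKM or more were kept, 10577 for DRRi against GFPi and 10699 for pHAN_DRR1.2 against pHAN_GFP. Changes are log2 of treated over control with a pseudocount of 1, which understates the change of weakly expressed genes; folds named in the text as thresholds are on this scale. With 1 library per group there are no replicates, so no p-value across genes was computed and each difference has no replicate check. A gene was counted at a change of 2-fold or more, and at 1.5-fold or more for overlaps between experiments. Each of 19 gene lists was described by the percentile of its median log2 change among 10000 random lists of the same size, matched on mean expression in 20 bins. A list whose median lies beyond the 2.5 or 97.5 percentile is said to lie outside the central 95%, as a description of these libraries. Adjustment over a list alone applies the Benjamini-Hochberg rule to the authors' p-values of the list's members. Counts adjusted in this way are not calls of the authors, and each p-value rests on 1 library per condition.

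Peak lists were compared by overlap of 1 bp or more, against 1000 circular shifts of a list along each chromosome. Intergenic means more than 5 kb from every gene locus of the expression tables, which carry no strand, and was compared with 100 shifts. Peaks were assigned to genes by a distance of 10 kb or less from the locus. Shares of changed genes were set against 10000 random gene sets matched on mean expression and locus length (6 bins each). Gene lists were taken whole, with unexpressed members, and their random genes were not limited to expressed ones. Shares have exact 95% Clopper-Pearson intervals, which cover counting error only. Random draws used seed 7. Coordinates are those of the files, mm9, counted from 1.

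The gene lists, thresholds, comparisons and the rule for naming genes were fixed before the data were examined. The rule takes Myod1 and Myog; the 10 genes with the highest and the 10 with the lowest log2 change among genes with a mean of 5 FPKM or more that the authors tested; up to 4 members of each list with the largest absolute change; every peak within 30 kb of Myod1 and Myog; the 5 highest peaks of each MyoD or MyoG list; and the number of peaks near members of 3 muscle lists. Single values of some genes that the rule takes are not reported here. The lists are myogenic regulators, sarcomere and contractile apparatus, excitation with synapse and muscle metabolism, fusion and adhesion, cell cycle, cell cycle exit, inhibitors of differentiation, immediate early response, interferon response, p53 response, unfolded protein and amino acid response, cholesterol synthesis, extracellular matrix and fibroblast markers, adipocyte and osteoblast markers, endothelial with blood and neural markers, housekeeping genes, RNA polymerase II and elongation machinery, cohesin with chromatin remodelling and histone modifiers, and mitochondrial respiratory chain.

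The alternatives tried were a pseudocount of 0.1, no filter and a filter at a mean of 5, centring on the median, the most abundant coding sequence alone, only coding sequences the authors tested, the authors' own significance call, a 2-fold threshold for the overlap of experiments, overlap of 50% of a peak, peaks up to 500 bp apart, the stricter 50% of each list by score or length, intergenic distances of 1 and 20 kb, and gene distances of 1 and 50 kb. An alternative that keeps the 50% of domains with the lowest false discovery rate was added after seeing the data.

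The calculations ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. They were first tested on simulated data, with 200 genes changed by known folds. The noise had 1 size for genes at any level, set from the spread of the real changes (0.272 and 0.141 on the log2 scale). Counts of unchanged genes that passed follow from that size and do not estimate chance calls. In the simulation of DRRi against GFPi (10443 genes), 83% of 2-fold and 95% of 3-fold changes passed 1.5-fold, and 176 unchanged genes did so too. In that of pHAN_DRR1.2 against pHAN_GFP (10618 genes) the shares were 96% and 97%, and 0 unchanged genes passed. Of 200 random lists of 20 genes drawn from the changes of these comparisons, 3% and 6.5% fell outside the central 95%, and 100% of lists shifted by 0.5 on the log2 scale were found above it in each. All 1000 planted peak overlaps were found, with a mean of the shifts that differed by 0.231% from its known value.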

Results

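C2C12 is a mouse myoblast line that exits the cell cycle and fuses into myotubes in low serum. The study asked how the transcription factors MyoD and MyoG and RNA made at enhancers act in this programme, with attention to the DRR, the distal regulatory region of the MyoD gene Myod1. Chromatin immunoprecipitation with sequencing (ChIP-seq) gave MyoD peaks in myoblasts and myotubes, MyoG peaks in myotubes, and domains of H3K4me1, a histone mark of enhancers, at both stages. PolyA RNA-seq was collected 4 h into differentiation from cells with RNAi against the DRR RNA (DRRi) or against GFP (GFPi), and from cells that overexpressed DRR RNA (pHAN_DRR1.2) or GFP (pHAN_GFP). Each group held 1 library, so there were no replicates and no difference between groups has a replicate check. Summed FPKM ranged from 383311 in pHAN_GFP to 411626 in DRRi, and 10516 to 10694 genes reached 1 FPKM per library. The read depth of the RNA libraries is unknown. The peak lists held 18141 MyoD peaks in myoblasts, 39700 MyoD peaks in myotubes and 35380 MyoG peaks, beside 66863 H3K4me1 domains in myoblasts and 70587 in myotubes.

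The first comparison asked what RNAi against the DRR RNA did to expression early in differentiation. Myog, the myogenic factor that drives terminal differentiation (chromosome 1, 136186580 to 136189125, mm9), was 3.92-fold lower in the DRRi library as a ratio of FPKM, at 2.61 against 10.2 in GFPi (log2 change with the pseudocount -1.64). Myod1 itself (chromosome 7, 53631843 to 53634462) stood at 33.1 FPKM against 37.7 (-0.18). Chrnd, a subunit of the acetylcholine receptor of the muscle endplate, was at 3.74 against 17.5 FPKM (-1.96), and Mylpf, the regulatory light chain of fast myosin, at 1.5 against 7.34 (-1.74). Enzymes of cholesterol synthesis were also lower in DRRi, while p53 target genes such as Ccng1 were higher, at 172 against 57.1 FPKM (1.57). In the authors' deposited table the q-value was 0.00848 for Myog, 1.00 for Myod1, 3.01e-06 for Chrnd and 3.00e-05 for Ccng1. The DRR RNA lies outside the coding tables, and its own level after RNAi was not analysed here.

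**Figure D1:**
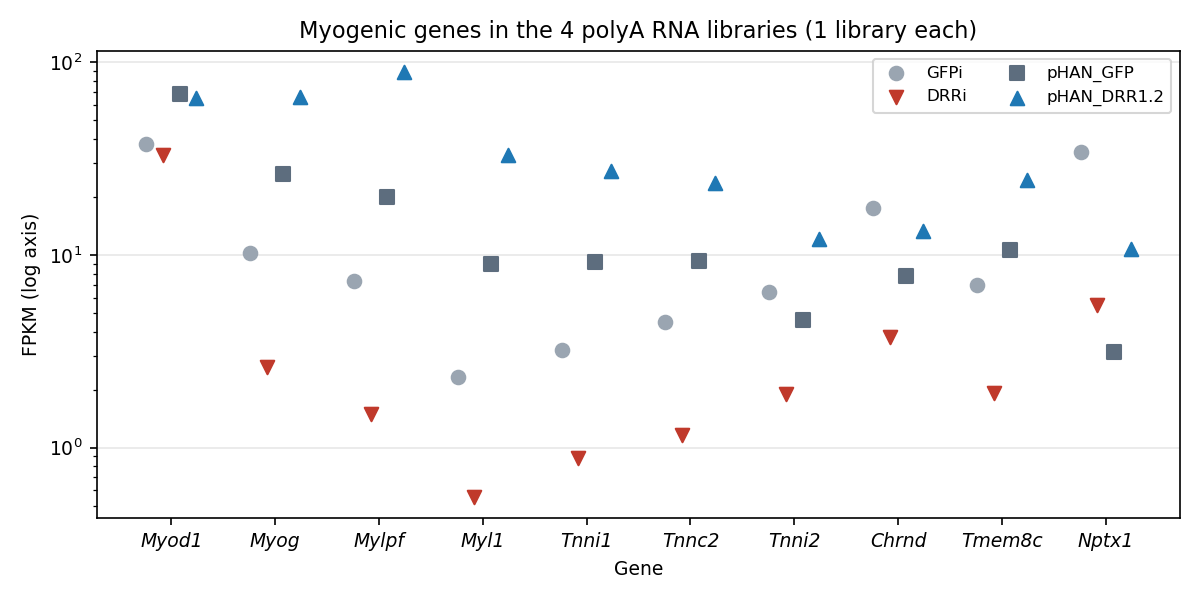
FPKM on a log axis of Myod1, Myog and 8 further genes in the 4 RNA libraries, with 1 point per library and no error bars, since each group held 1 library. Myog was at 2.61 FPKM in DRRi against 10.2 in GFPi and at 65.8 in pHAN_DRR1.2 against 26.3 in pHAN_GFP, and the levels of the 2 experiments were normalized separately.

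Of 10577 genes, 95 were 2-fold or more higher and 85 were 2-fold or more lower in DRRi than in GFPi. With a pseudocount of 0.1 these counts were 180 and 132, and among genes with a mean of 5 FPKM or more they were 60 and 53. At 1.5-fold the counts were 493 and 370. In a simulation of this comparison 176 unchanged genes passed that size. Its noise had 1 size for all genes, set from the spread of these same changes, so 176 is no estimate of chance calls. The authors' deposited table called 85 genes higher and 71 lower at its q threshold, of which 56 and 54 also passed 2-fold.

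Among genes with a mean of 5 FPKM or more, those furthest below GFPi were led by Nptx1, a secreted neuronal pentraxin, at 5.52 against 34.3 FPKM (-2.44). Ndrg4 was at 10.8 against 44.7 FPKM (-1.95). Igfbp5, an IGF-binding protein abundant in differentiating muscle cells, was at 237 against 760 FPKM (-1.68), and Igfbp3 at 4.38 against 15.1 (-1.58). Nme4 (-1.64), Dmp1 (-1.61) and Cd24a (-1.55) were also among the 10 lowest, with Chrnd and Myog. At the other end of these genes, Rpl35, a protein of the large ribosomal subunit, was at 976 FPKM in DRRi against 3.55 in GFPi (7.75), and it was also scarce in the other GFP control, at 2.66 in a table normalized separately. Next came Akr1b3, an aldose reductase, at 11.2 against 1.89 (2.08), for which the authors' deposited table gave a q of 1.00. Eda2r, of the tumour necrosis factor receptor family, was at 29.2 against 6.82 FPKM (1.95). Inhbb, an activin subunit, was at 9.92 against 1.92 (1.90), and Sfrp2, a secreted modulator of Wnt signalling, at 26.1 against 6.69 (1.82). Loxl2 (1.80), Dcxr (1.80), Sulf2 (1.77), 9030617O03Rik (1.68) and Chac1 (1.62) followed.

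Muscle lists lay below their matched random lists in DRRi. Of 20 measured sarcomere genes, 9 were 1.5-fold or more lower and 1 higher, with a median log2 change of -0.30, below all 10000 random lists. Besides Mylpf, the troponin genes Tnni2 (1.90 against 6.46 FPKM, -1.36), Tnnc2 (1.16 against 4.49, -1.34) and Tnni1 (0.887 against 3.21, -1.16) were the furthest down. Among 10 sarcomere genes with a mean of 5 FPKM or more the median was at percentile 8.22, inside the central 95%. Genes of excitation, synapse and muscle metabolism had 7 of 16 members lower and 0 higher, with a median of -0.41 below all random lists. They included Chrnd, Chrng (1.18 against 4.69 FPKM, -1.39), Cacng1 (42.3 against 90.1, -1.07) and Musk, the agrin-responsive kinase of the neuromuscular synapse (5.93 against 12.2, -0.93). In the authors' deposited table, 1 sarcomere gene and 3 excitation genes were called lower over all genes. Its p-values, adjusted here over each list alone, gave 7 and 5, which are not calls of the authors.

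Myogenic regulators had a median of -0.18 (percentile 0.75), with 3 of 15 genes 1.5-fold or more lower and 0 higher. These were Myog, Rbm24, an RNA-binding protein of muscle (1.66 against 7.25 FPKM, -1.63), and the homeobox gene Six4 (8.16 against 15.8, -0.88). Fusion and adhesion genes had a median of -0.15 (percentile 1.57), with 3 of 20 genes lower and 2 higher. Tmem8c, which encodes the fusion protein myomaker, was at 1.91 against 7.01 FPKM (-1.46), Jam2 at 18.4 against 31.9 (-0.76), Itga7 at 46.8 against 74.3 (-0.66) and Jam3 higher at 14.7 against 8.28 (0.76). The authors' deposited table called 2 genes lower in each list, and 3 in each when adjusted over the list alone. The regulators came to percentile 6.31 with a mean of 5 FPKM or more and 12.5 with no filter, and the fusion genes to 12.9 and 6.31 in turn and to 8.5 with the most abundant coding sequence alone, all inside the central 95%.

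Genes of cholesterol synthesis stood lower as a group in DRRi, with a median of -0.58 below all 10000 random lists and 22 of 23 members below 0. At 1.5-fold, 11 were lower, among them Cyp51 (43.2 against 90.9 FPKM, -1.06) and Tm7sf2 (3.21 against 7.59, -1.03). The authors' deposited table called 3 of them lower, and 6 when adjusted over the list alone. Genes of the mitochondrial respiratory chain had a median of -0.17 (percentile 0.12), with 27 of 33 below 0 and 0 past 1.5-fold. The lowest included Ndufa4 (394 against 579 FPKM, -0.56) and Uqcrh (302 against 416, -0.46).

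The p53 response list had the highest median in DRRi, 0.92, above all 10000 random lists. Of 19 measured genes, 16 were 1.5-fold or more higher and 0 lower. Gdf15, a stress-induced cytokine, was at 7.56 against 1.59 FPKM (1.73), Trp53inp1 at 14.7 against 5.06 (1.37) and Sesn2, an inhibitor of mTORC1 signalling, at 11.6 against 3.97 (1.35), beside Ccng1. Cdkn1a, the inhibitor of cyclin-dependent kinases known as p21, was at 146 against 71.1 FPKM (1.03), with a q of 0.0289 in the authors' deposited table. That table called 8 of the p53 genes higher. Its p-values, adjusted here over the list alone, gave 15. Cdkn1a and Btg2 also belong to the cell cycle exit list, Btg2 to the immediate early list and Sesn2 to the unfolded protein and amino acid list.

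Immediate early genes had a median of 0.35, above all random lists, with 8 of 26 genes higher and 1, Egr3 (-0.64), lower. Ctgf, a matricellular protein gene, was at 8.24 against 2.70 FPKM (1.32) and Ier3 at 14.7 against 7.69 (0.85), and the authors' deposited table called 1 gene higher, as it did when adjusted over the list alone. The unfolded protein and amino acid list had a median of 0.20 (percentile 99.8), with 7 of 22 higher and 2 lower. Its higher members included Chac1, Ddit4 (45.3 against 16.3 FPKM, 1.42), Trib3 (7.62 against 2.29, 1.39) and Sesn2, genes of the response to amino acid shortage. The chaperone genes Hspa5 (-0.53), Dnajb9 (-0.61) and Creld2 (-0.71), named after their values were seen, lay below 0. The authors' deposited table called 4 genes of this list higher, and 5 when adjusted over the list alone. With a mean of 5 FPKM or more the list came to percentile 51.3, inside the central 95%.

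The other lists lay inside the central 95% for DRRi. Cell cycle genes had a median of 0.00 (percentile 58.3), with Ccne2 (17.7 against 32.8 FPKM, -0.86) below and Tyms (15.8 against 8.93, 0.76) above GFPi. Cell cycle exit genes were at -0.04 (percentile 21.7), in spite of Cdkn1a and Btg2 (9.45 against 5.19 FPKM, 0.76). Inhibitors of differentiation were at 0.16 (percentile 95.1), with the Notch effector Heyl at 1.33 against 7.23 FPKM (-1.82) and the receptor gene Notch1 at 15.7 against 7.64 (0.96). Extracellular matrix and fibroblast markers were at 0.11 (percentile 93.6), and 5 of 22 were higher, such as Col1a1 (14.2 against 4.32 FPKM, 1.51), Postn (5.33 against 1.43, 1.38) and Tagln (51.9 against 24.5, 1.06), with Sparc lower (454 against 795, -0.81). Calls of the authors' deposited table in these lists were 2 matrix genes, 1 exit gene and 1 inhibitor higher and 1 inhibitor lower, with equal counts when adjusted over the list alone, and 0 cell cycle genes were called. Interferon response genes were at 0.26 (percentile 96.6) with 0 of 11 past 1.5-fold, and reached percentile 98.0 with a pseudocount of 0.1 and 97.7 with no filter, outside the central 95%.

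Markers of adipocytes and osteoblasts (median -0.05, percentile 24.3), with Spp1 at 1351 against 1696 FPKM (-0.33), stayed within the range in DRRi. So did endothelial, blood and neural markers (0.12, percentile 68.8), of which 3 were measured, with Tubb3 at 35.5 against 24.5 FPKM (0.52). Housekeeping genes were at 0.08 (percentile 83.5), with B2m at -0.39 and Rplp0 at 0.36. Genes of RNA polymerase II and the elongation machinery were at -0.02 (percentile 33.0), with Ell at 0.55, and genes of cohesin, chromatin remodelling and histone modification at -0.05 (percentile 14.3), with the arginine methyltransferase gene Carm1 at 0.88. The authors' deposited table called 0 genes of these 5 lists, of the mitochondrial list and of the interferon list, over all genes or adjusted over the list alone.

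**Figure D2:**
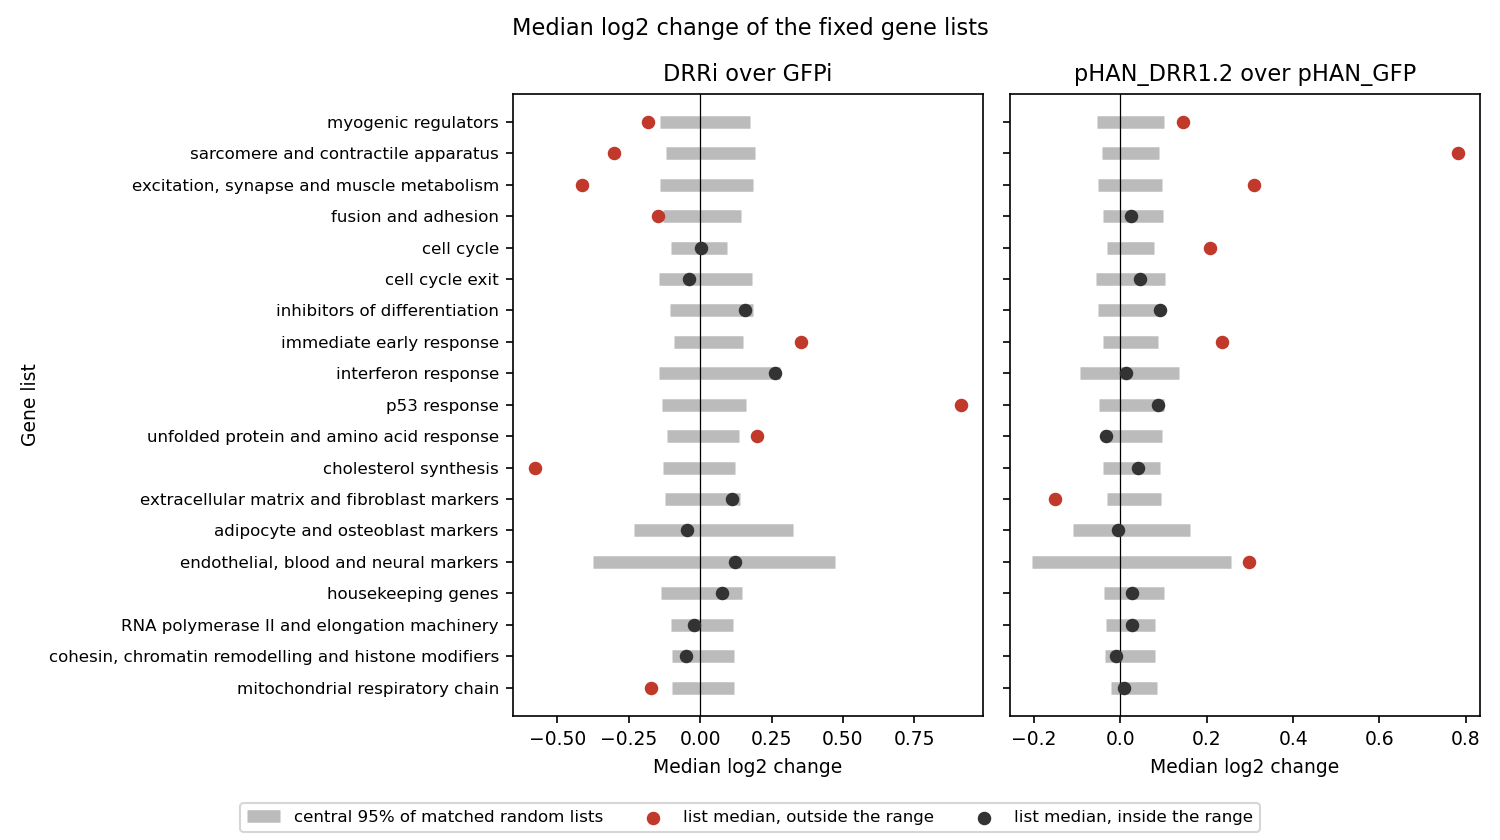
Median log2 change of 19 gene lists in DRRi over GFPi (left) and in pHAN_DRR1.2 over pHAN_GFP (right), with grey bars for the central 95% of 10000 random lists matched on expression and red points for medians outside them. In DRRi, 9 lists lay outside, from cholesterol synthesis at -0.58 to the p53 response at 0.92, and in pHAN_DRR1.2 7 did, with the sarcomere list highest at 0.78.

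The second comparison asked what overexpression of DRR RNA did, in particular to early activation of Myog. In the pHAN_DRR1.2 library Myog was 2.5-fold higher as a ratio of FPKM, at 65.8 against 26.3 in pHAN_GFP (log2 change with the pseudocount 1.29), while Myod1 was at 65.6 against 68.9 (-0.07). Mylpf stood at 89.2 against 20.1 FPKM (2.10) and Myl1, an essential light chain of fast myosin, at 32.9 against 8.97 (1.77). Sfrp2, higher in DRRi, was lower here, at 23.7 against 75.8 FPKM (-1.64). In the authors' deposited table the q-value was 1.38e-08 for Myog, 1.00 for Myod1 and 4.15e-07 for Myl1, and was printed as 0 for Mylpf and Sfrp2.

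Of 10699 genes, 34 were 2-fold or more higher and 9 were 2-fold or more lower in pHAN_DRR1.2. These counts were 67 and 30 with a pseudocount of 0.1, 21 and 5 among genes with a mean of 5 FPKM or more, and 52 and 26 with the most abundant coding sequence alone. At 1.5-fold, 148 genes were higher and 70 lower. The authors' deposited table called 119 genes higher and 74 lower, of which 33 and 7 also passed 2-fold.

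Apart from Rpl35 (659 against 2.66 FPKM, 7.50), the 10 highest genes with a mean of 5 FPKM or more were led by contractile proteins. They included Mylpf, Myl1, Tnni1 (27.2 against 9.20 FPKM, 1.47), Tnnc2 (23.7 against 9.26, 1.26), Tnni2 (12.2 against 4.58, 1.24) and Myog. Nptx1, the lowest such gene in DRRi, was at 10.7 against 3.13 FPKM (1.5), Alox5, a lipoxygenase of leukotriene synthesis, at 67.7 against 27.1 (1.29), and Dync1i1, a dynein intermediate chain, at 15.1 against 6.17 (1.17). The lowest genes with that mean were Lars2, the mitochondrial leucyl-tRNA synthetase (52.4 against 195 FPKM, -1.88), Sfrp2, the polysialyltransferase St8sia2 (6.83 against 17.2, -1.22) and the imprinted gene Mest (48.7 against 114, -1.22). Cnn1, a calponin of smooth muscle (7.76 against 17.3 FPKM, -1.06), Igdcc4 (5.39 against 11.8), C1qtnf3 (-0.99), Gas6 (11.4 against 23.5, -0.98), Aoc3 (-0.92) and Fmo1 (-0.91) followed. For C1qtnf3 the authors' deposited table gave a q of 0.705.

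Of 26 measured sarcomere genes, 15 were 1.5-fold or more higher in pHAN_DRR1.2 and 0 lower, with a median of 0.78, above all 10000 random lists. Beside the light chains and troponins they included Mybph, a myosin-binding protein (6.38 against 1.51 FPKM, 1.56), and the embryonic heavy chain gene Myh3 (4.79 against 1.01, 1.52). Genes of excitation, synapse and muscle metabolism had 7 of 22 members higher and 0 lower (median 0.31, above all random lists), with Casq2, a calcium store protein (3.01 against 0.772 FPKM, 1.18), Ckm, muscle creatine kinase (1.80 against 0.502, 0.90), Atp2a1, the calcium pump of fast fibres (6.60 against 3.62, 0.72), and Chrnd (13.3 against 7.75, 0.71). Of the sarcomere genes 12, and of the excitation genes 3, were called higher in the authors' deposited table, and 14 and 8 when adjusted over the list alone. Myogenic regulators had a median of 0.15 (percentile 99.9), with Myog 1.5-fold or more higher and Rbm24 lower (7.11 against 12.6 FPKM, -0.74), and the authors' deposited table called 1 gene each way, also when adjusted over the list alone. The regulators came to percentile 65.9 with a mean of 5 FPKM or more and 89.2 with the most abundant coding sequence alone, inside the central 95%.

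All 35 measured cell cycle genes lay above 0 in pHAN_DRR1.2, with a median of 0.21 above all random lists, and 1 passed 1.5-fold: Tyms, thymidylate synthase, at 6.91 against 2.68 FPKM (1.10). Plk1, a mitotic kinase, was at 24.2 against 18.3 (0.39). Immediate early genes had a median of 0.24, above all random lists, with 3 of 27 higher, namely Dusp6 (29.6 against 18.2 FPKM, 0.67), Klf2 (8.99 against 5.29, 0.67) and Fosl1 (29.2 against 18.8, 0.61). The authors' deposited table called 1 gene of each of these lists higher, also when adjusted over the list alone. Extracellular matrix and fibroblast markers had a median of -0.15, below all random lists, with 3 of 24 lower and 1 higher. Cnn1, Mmp2 (88.8 against 147 FPKM, -0.73) and Postn (13.8 against 22.6, -0.67) were lower and the proteoglycan gene Dcn was higher (7.78 against 3.02, 1.13). The authors' deposited table called 2 matrix genes lower and 1 higher, and 4 and 2 when adjusted over the list alone. Of the 3 measured endothelial, blood and neural markers, all lay above 0 (median 0.30, percentile 98.6), with the tubulin gene Tubb3 at 91.0 against 51.0 FPKM (0.82), called higher in the authors' deposited table. With no filter on low values that list came to percentile 32.0.

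The remaining lists lay inside the central 95% for pHAN_DRR1.2. Fusion and adhesion genes were at percentile 49.6, although Tmem8c stood at 24.5 against 10.6 FPKM (1.14), and inhibitors of differentiation at percentile 97.2, with the Krueppel-like factor gene Klf4 at 20.3 against 12.2 (0.68). The authors' deposited table called 1 gene of each list higher, also when adjusted over the list alone. The inhibitors came outside, to percentile 97.7 with a pseudocount of 0.1 and 99.9 with a mean of 5 FPKM or more. The p53 list was at percentile 95.4, with Pmaip1, a pro-apoptotic BH3-only gene, at 9.29 against 5.36 FPKM (0.70), and the authors' deposited table called 0 of its genes, or 1 higher when adjusted over the list alone. The unfolded protein and amino acid list was at percentile 4.21, with Sdf2l1 at -0.42, and came outside at 0.14 with no filter and 2.29 with a mean of 5 FPKM or more. Cell cycle exit (percentile 74.0, Gas1 at -0.44), interferon response (47.2, Isg15 at -0.24), cholesterol synthesis (67.1, Sqle at 0.15) and adipocyte and osteoblast markers (36.2, Spp1 at 3103 against 2135 FPKM, 0.54) lay within. So did housekeeping genes (49.2, Tubb5 at 0.20), polymerase II and elongation (54.8, Cdk7 at -0.27), cohesin and chromatin genes (13.1, Smarca2 at -0.35) and the respiratory chain (18.5, Ndufa1 at -0.24). The authors' deposited table called 0 genes of the unfolded protein list and of these 8 lists, over all genes or adjusted over the list alone.

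RNAi against the DRR RNA and its overexpression were then set side by side, to ask which genes went opposite ways. Among 10398 genes measured in both experiments, 26 were 1.5-fold or more lower in DRRi and higher in pHAN_DRR1.2, where independent lists would give 3.83. Of these, 12 belonged to the lists of myogenic regulators, sarcomere, excitation or fusion genes, among them Myog, Mylpf, Myl1, Tnni1, Tnni2, Tnnc2, Tnnt3, Atp2a1, Chrnd and Tmem8c, and Nptx1 was outside those lists. In the other direction, 8 genes were higher in DRRi and lower in pHAN_DRR1.2 (2.21 for independent lists): Sfrp2, Sfrp1, Gas6, Postn, Cnn1, Akr1b3, Adamts10 and Cacng7. Of these opposite genes, only Myog, Mylpf, Chrnd, Tmem8c, Nptx1 and Sfrp2 had a q under 0.05 in both experiments in the authors' deposited table. In DRRi the q was 0.308 for Myl1, 0.288 for Tnni1, 0.195 for Tnni2, 0.168 for Tnnc2 and 0.639 for Atp2a1. In pHAN_DRR1.2 it was under 0.05 for these genes except Atp2a1 (0.182). For Akr1b3, Adamts10, Tnnt3, Glipr1 and Gm6985 it was 1.00 in both experiments. Adamts10 was near 0 FPKM in GFPi and in pHAN_DRR1.2. Genes that went the same way came to 22 higher in both (5.01 for independent lists) and 18 lower in both (1.69). The 34 opposite genes were thus 5.63 times and the 40 same-way genes 5.97 times the independent count. That count takes every gene as equally likely to pass 1.5-fold. Genes more variable than others would raise both ratios, so the excess alone shows neither an opposite nor a shared response. Across genes, which are not independent replicates, the changes had r = 0.096 and Spearman's rho = 0.082. Rpl35 (7.75 and 7.50) weighs on r, which was not computed without it. With a mean of 5 FPKM or more 10 genes went opposite ways and 23 the same way, and of the 12 muscle and fusion genes 2, Chrnd and Myog, were left, while at 2-fold 10 went opposite ways and 3 the same way. With a pseudocount of 0.1 the opposite genes were 63, and with the most abundant coding sequence alone 53. The experiments had separate control libraries.

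**Figure D3:**
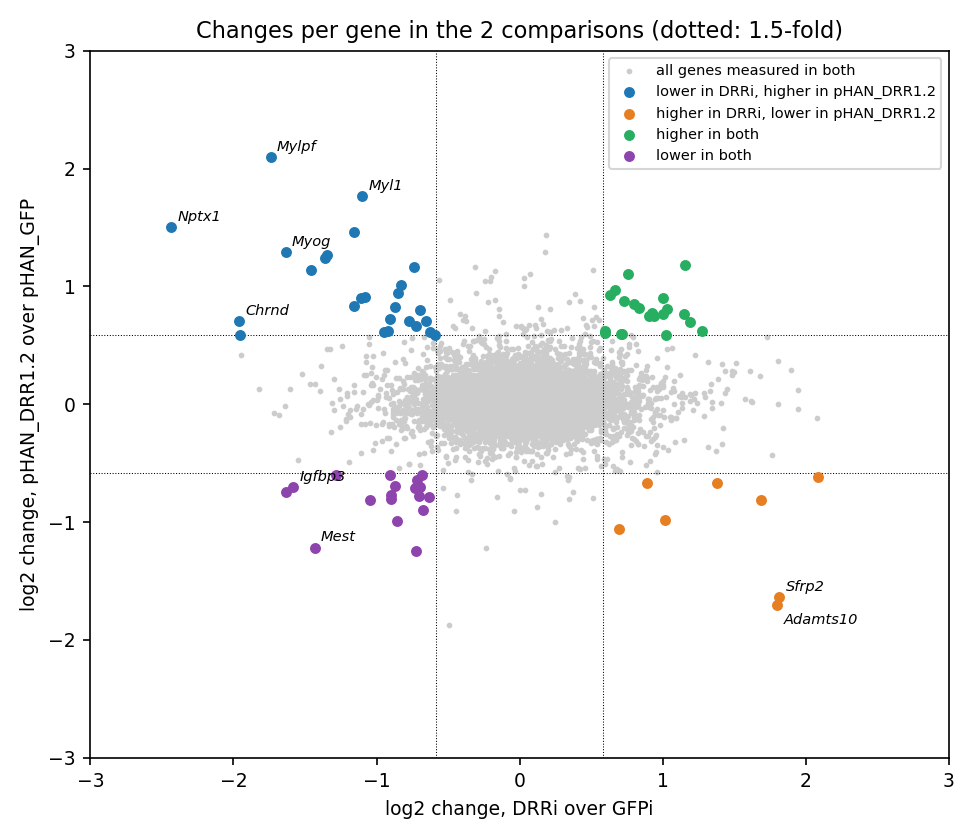
Log2 change in DRRi over GFPi (x axis) against log2 change in pHAN_DRR1.2 over pHAN_GFP (y axis) for 10398 genes, with 1 point per gene, dotted lines at 1.5-fold and colours for genes past that size in both, and with Rpl35 (7.75 and 7.50) beyond the axes. Muscle genes such as Mylpf (-1.74 and 2.10) lie at the upper left, Sfrp2 (1.82 and -1.64) at the lower right and Mest (-1.43 and -1.22) at the lower left.

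Binding of MyoD was compared between myoblasts and myotubes, to see which sites are held before differentiation. Of 39700 MyoD peaks in myotubes, 13527 overlapped a MyoD peak of myoblasts (34.1%, exact 95% interval 33.6 to 34.5), against a mean of 1.29% for shifted peaks. In turn, 73.9% of the myoblast peaks were found again in myotubes. Shared myotube peaks had a median score of 404 and myotube-only peaks of 130, as scored by the authors. A myotube-only peak is one without a called peak in the myoblast list, which was shorter (18141 peaks). ChIP depths were not compared, so weak myoblast sites may have been missed. MyoG, which appears when cells differentiate, largely sat at MyoD sites: 27442 of 35380 MyoG peaks overlapped a myotube MyoD peak (77.6%, 77.1 to 78, against 2.39%). MyoD peaks that overlapped a MyoG peak had a median score of 271, and those that did not, 97.2. In this and the following overlaps 0 of 1000 shifts came as high (permutation p = 0.001, one-sided, the smallest possible). That p-value was equal in all 12 overlaps computed and so is left as it is by adjustment. Shifts place peaks anywhere along a chromosome, whether or not reads can be mapped there or chromatin is open. The p-value therefore speaks against random placement only and is no test of specific co-binding or marking.

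H3K4me1 was compared between the stages and with the binding sites, to ask whether bound sites lay in marked chromatin. The mark covered 208 Mb in myoblasts and 236 Mb in myotubes. Of the myotube domains, 48187 overlapped a myoblast domain (68.3%, 67.9 to 68.6, against 15.9% for shifts). MyoD peaks lay inside domains of their own stage in 86.7% of cases in myoblasts (86.2 to 87.2, shifts 11.2%) and 85.0% in myotubes (84.7 to 85.4, shifts 12.4%), and MyoG peaks in 84.5% (84.1 to 84.8, shifts 11.8%). Of the 26173 MyoD peaks called in myotubes and not in the shorter myoblast list, 12678 lay in chromatin that carried H3K4me1 in myoblasts already (48.4%, 47.8 to 49.0, shifts 10.9%), and 81.9% lay in marked chromatin of myotubes. With the 50% of domains of lowest false discovery rate, an alternative chosen after seeing the data, 8140 of them lay in myoblast domains.

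Myotube domains that overlapped a myoblast domain held a myotube MyoD peak in 37.4% of cases (37.0 to 37.8) and a MyoG peak in 33.8% (33.3 to 34.2). Myotube domains with no called myoblast domain (myotube-only) held them in 31.3% (30.7 to 32.0) and 25% (24.4 to 25.6). Myoblast domains with no called myotube domain (myoblast-only) held a myotube MyoD peak in 3.72% (3.45 to 4.00) and a myoblast MyoD peak in 5.83% (5.50 to 6.18). Such domains of 1 stage had lower median folds than shared ones (2.41 against 2.85 in myotubes, 2.24 against 2.35 in myoblasts). They were also shorter (medians of 2000 and 1600 bp against 2600 bp). H3K4me1 depths were not compared, so weak domains of the other stage may have been missed. Per Mb of domain there were 150 myotube MyoD peaks in myotube-only domains, 141 in myotube domains that overlapped a myoblast domain, and 20.7 in myoblast-only domains. For MyoG these densities were 119, 129 and 19.98. Peaks more than 5 kb from every gene locus made up 43.8% of MyoD peaks in myoblasts (7949 peaks, 43.1 to 44.5), 36.6% in myotubes (14532) and 37.0% of MyoG peaks (13104), each below the 56.6%, 56.3% and 56.3% of shifted peaks. H3K4me1 domains of the same stage held 86.5%, 84.8% and 83.2% of these intergenic peaks.

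**Figure D4:**
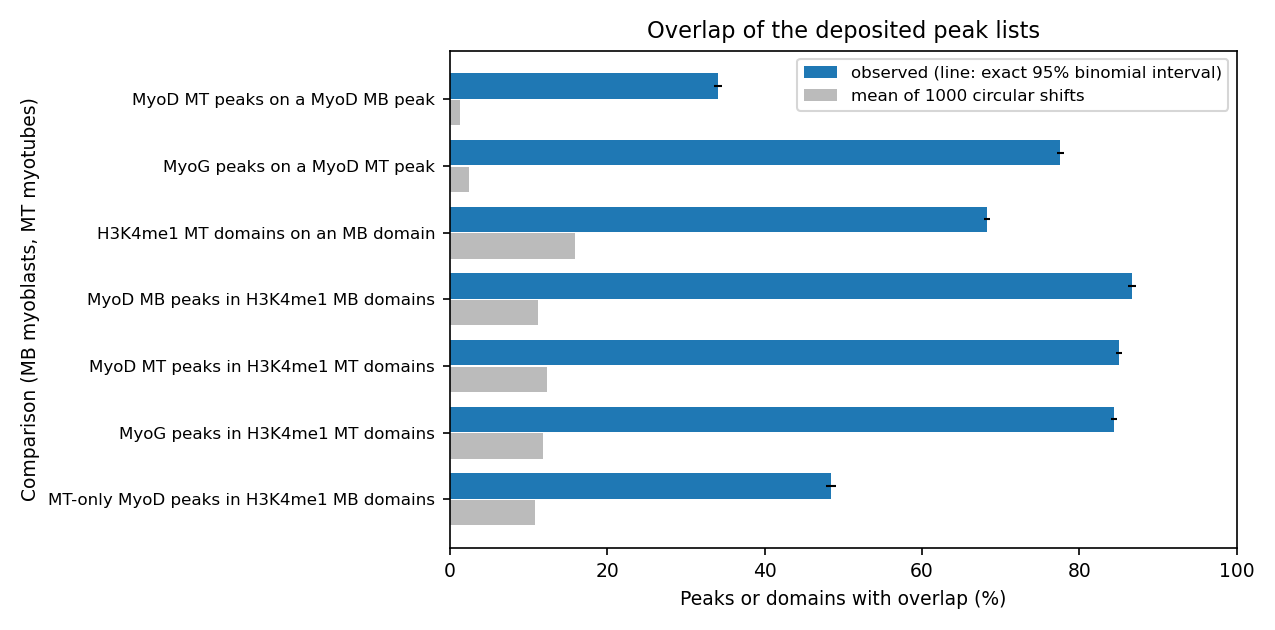
Percent of peaks or domains of a list that overlapped another list (bars, from 0) with exact 95% intervals, beside the mean of 1000 circular shifts. Observed shares run from 34.1% for MyoD peaks of myotubes on those of myoblasts to 86.7% for MyoD peaks of myoblasts in H3K4me1 domains, and the shifted means from 1.29% to 15.9%.

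Around Myod1 itself, within 30 kb, there were 3 MyoD peaks in myoblasts, 12 in myotubes and 9 MyoG peaks. Such counts, also those around Myog, rest on lists of unequal length (18141 and 39700 MyoD peaks), whose ChIP depths were not compared. In myoblasts, MyoD peaks lay 25.9 and 23.2 kb to the left of the locus on the map (chromosome 7, 53605294 to 53606630 and 53608037 to 53609280, mm9), and a myotube peak overlapped each, inside an H3K4me1 domain at both stages. Nearer, 5.2 kb to the left, myotubes had a MyoD peak (53626192 to 53627045) and a MyoG peak (53626332 to 53627001) where myoblasts had none called. That site lay in a myotube H3K4me1 domain (53615401 to 53631400) and outside the nearest myoblast domain (53616601 to 53624800). The sources used here give no coordinates of the DRR, so no peak was assigned to it. Domains that reached into this window covered 18200 bp in myoblasts and 50400 bp in myotubes, counted over their full length.

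Around Myog there were 3 MyoD peaks in myoblasts, 18 in myotubes and 13 MyoG peaks, and domains of 3800 bp in myoblasts against 73000 bp in myotubes. A MyoD peak lay over the start of Myog on the map at both stages, from 136186074 to 136186726 in myoblasts (score 92.24) and from 136185805 to 136187937 in myotubes, where its score was at the ceiling of the list. MyoG was bound there too (136185933 to 136186876). In myotubes a domain of 23400 bp (136168201 to 136191600) spanned the gene, while the 2 myoblast domains (136179201 to 136181600 and 136183601 to 136185000) lay to its left. The highest-scoring peaks genome-wide lay in or nearest to Ttll11, Lrig1, Prep, Ahdc1 and Cd44 for MyoD in myoblasts, and Tnp1, Arhgap28, Flrt1, Serpinh1 and Rgs8 for MyoD in myotubes. For MyoG they lay in or nearest to Ccna2, Pigp, Ltbp2, Arhgef2 and Gadd45g, the last at 176273 bp.

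Muscle genes lay beside these sites. All 41 sarcomere genes had a MyoD peak of myotubes and a MyoG peak within 10 kb, and 29 had a MyoD peak in myoblasts. Random genes, expressed or not, had them in 58.2%, 54.7% and 33.6% of cases. Among the 10398 genes measured in both RNA experiments the shares were higher, at 74.2%, 70.2% and 45.1%. Myl1 had 1 MyoD peak in myoblasts and 9 in myotubes, and Mylpf 0 and 4. Of 28 genes of excitation, synapse and muscle metabolism, 23 had a MyoD peak in myoblasts, 27 in myotubes and 28 a MyoG peak, and of 20 myogenic regulators 16, 17 and 17 did. Genes past 1.5-fold in the RNA comparisons had any MyoD or MyoG peak within 10 kb in 82.8% of 493 genes higher in DRRi (79.1 to 86.0, matched random genes 79.4%), 84.1% of 370 lower in DRRi (79.9 to 87.6, 80.7%), 83.8% of 148 higher in pHAN_DRR1.2 (76.8 to 89.3, 78.5%) and 88.6% of 70 lower there (78.7 to 94.9, 81.0%). Their percentiles among 10000 random gene sets, 96.8, 95.3, 94.7 and 95.3, were inside the central 95%, as a description of these libraries. With the stricter 50% of each list, 3 sets came outside, with 61.9% of genes higher in DRRi (random 56.1%, percentile 99.6), 65.7% of genes lower in DRRi (57.7%, 99.965) and 69.6% of genes higher in pHAN_DRR1.2 (55.2%, 99.985). Within 1 kb, genes lower in pHAN_DRR1.2 came outside, at 80% (69.8%, 97.8). Near MyoG peaks alone, a split outside the plan, the first 3 sets were also outside, at 72.0% (68.0%, 97.8), 74.1% (69.5%, 97.7) and 74.3% (67.1%, 97.6), and genes lower in pHAN_DRR1.2 inside, at percentile 57.0. Near MyoD peaks of myotubes alone, genes lower in DRRi were outside, at 79.5% (73.7%, percentile 99.5), and the other sets inside, at percentiles 91.9, 96.7 and 81.7.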

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

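Tests with the domains of lowest false discovery rate were chosen after the result was seen. No paired analysis was possible because each group held 1 sample, so no result came from a test across replicates. Of 110 alternatives over 25 results, 69 left the value within its limits and 41 moved it. A reversed direction could be called only for the Myog changes, of which 0 reversed. Counts and shares have no sign. The Myod1 changes were smaller than the standard error that served as their limit, so the rule could not call them reversed. The limits were 1.5 times for a count, the exact 95% interval for a share and, for a gene's log2 change, the standard error implied by the p-value in the authors' deposited table. Myod1 and Myog changes stayed within theirs under a pseudocount of 0.1 and centring. The most abundant coding sequence alone gave identical values for these genes, so it was no test of them. Centring on the median and tested coding sequences alone moved 0 results, as did overlap of 50% of the peak, gaps of up to 500 bp and intergenic limits of 1 and 20 kb. With no filter on low values all counts stayed within their limits, but the call of 3 lists in DRRi and of 2 in pHAN_DRR1.2 changed. A pseudocount of 0.1 gave 180 genes 2-fold higher and 132 lower in DRRi, 67 and 30 in pHAN_DRR1.2, and 63 in opposite directions. A mean of 5 FPKM or more left fewer genes and gave 60 and 53, 21 and 5, and 10 opposite, with 5 DRRi lists outside the central 95%. The most abundant coding sequence alone gave 52 and 26 for pHAN_DRR1.2 and 53 opposite. The authors' deposited significance call, which has no fold limit, gave 119 and 74 there. A 2-fold limit left 10 opposite genes. The stricter 50% of each list holds fewer peaks. There 6728 myotube MyoD peaks overlapped a myoblast peak, 13997 MyoG peaks a MyoD peak and 21388 myotube domains a myoblast domain. Inside domains lay 7067 myoblast MyoD peaks, 15151 myotube MyoD peaks, 13474 MyoG peaks and, of myotube-only MyoD peaks, 5326 in myoblast domains. Intergenic peaks numbered 3976, 7342 and 6597. Domains of lowest false discovery rate gave 21006 shared domains and 8140 myotube-only MyoD peaks in myoblast domains. Of genes higher and lower in DRRi and higher and lower in pHAN_DRR1.2, 61.9%, 65.7%, 69.6% and 62.9% lay near a peak of the stricter lists, against 56.1%, 57.7%, 55.2% and 59.3% of random genes, which put the first 3 sets outside the central 95%. For the first 3 of these sets a limit of 1 kb gave 69.4%, 71.4% and 70.3%, and 50 kb gave 94.5%, 94.1% and 93.2%. Genes past 2-fold gave 75.8% for higher in DRRi and 77.8% for lower in pHAN_DRR1.2. Where fewer genes or peaks or another distance limit is not the reason, the cause was not tested. With no read depth given for the RNA libraries, the counting error of weakly expressed genes is unknown.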

Other observations

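Tests of the p53 pattern, the look at genes near MyoD peaks of myoblasts alone, the other peak shares of the second paragraph and the genes named in this paragraph were chosen after the result was seen. Examples of the 18 genes lower in both DRRi and pHAN_DRR1.2 follow, with no theme tested among them. Mest, an imprinted gene expressed from the paternal allele, was at 43.4 FPKM in DRRi against 119 in GFPi and at 48.7 in pHAN_DRR1.2 against 114 in pHAN_GFP. Ogn, a small proteoglycan gene, was at 46.5 against 72.8 and at 499 against 862, and Car3, a carbonic anhydrase of muscle and fat, at 25 against 62.1 and at 165 against 251. Fgfr4, a growth factor receptor of myogenic cells, was at 9.37 against 16.2 and at 15.4 against 25.8. Among the 22 genes higher in both, Ly6a, which encodes the surface antigen Sca-1, was at 104 against 62.9 and at 274 against 180 FPKM. The ETS factor gene Etv4 (27.6 against 13.1, then 15.3 against 9.82), Dusp4 (23.4 against 13.7, then 21.7 against 11.4), a phosphatase gene, and Areg (10.8 against 5.65, then 9.04 against 4.72) were higher in both as well.

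MyoD peaks of myoblasts, called before differentiation, lay near the genes that differed in all 4 sets. They were within 10 kb of 50.7% of genes higher and 56.2% of genes lower in DRRi, where matched random sets gave 43.8% and 44.9% (percentiles 99.9 and 100). In pHAN_DRR1.2 the shares were 68.2% of genes higher and 70.0% of genes lower, against 43.4% and 47.7% (percentiles 100 and 99.99). Of the 26 genes lower in DRRi and higher in pHAN_DRR1.2, 22 had such a peak (84.6%, exact 95% interval 65.1 to 95.6, random 43.8%, percentile 100). The other sets were inside the central 95%, with 4 of 8 genes higher in DRRi and lower in pHAN_DRR1.2 (percentile 76.1), 11 of 22 higher in both (87.6) and 12 of 18 lower in both (95.8). Of the lists outside muscle and fusion, 5 lay above the central 95% for MyoD peaks of myotubes: immediate early genes (24 of 28, random 46.0%), inhibitors of differentiation (20 of 26, 50.5%), p53 response (17 of 20, 55.6%), unfolded protein and amino acid response (20 of 23, 53.5%) and polymerase II with elongation (26 of 31, 57.9%). The random genes of these and the other lists were not limited to expressed ones. Of the 10398 genes measured in both experiments, 74.2% had a MyoD peak of myotubes. Beside that share, inhibitors were at 76.9% and polymerase II at 83.9%, a difference that was not tested. For MyoD peaks of myoblasts the unfolded protein and polymerase lists were inside (percentiles 74.8 and 31.5), and for MyoG peaks the inhibitors and the polymerase list (97.255 and 93.3). Extracellular matrix and fibroblast markers lay above for MyoD peaks of myoblasts (18 of 27, random 36.5%, percentile 99.9) and inside for those of myotubes (96.1). Interferon response genes had a MyoD peak of myoblasts in 6 of 33 cases (percentile 7.16), one of myotubes in 16 (19.8) and a MyoG peak in 10 (0.575).

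Rpl35 was at 976 and 659 FPKM in DRRi and pHAN_DRR1.2 but at 3.55 and 2.66 in GFPi and pHAN_GFP, and it was the 1 gene of 1570 and 1462 at 50 FPKM or more that differed by 10-fold or more. The next largest differences, with the pseudocount, were 3.20-fold (Igfbp5) and 4.28-fold (Mylpf). The missing value was not held by a neighbour or a copy in the table, since at most 0.631% of it appeared as an excess in the control among loci within 100 kb or genes named like Rpl35. A lower level of ribosomal protein transcripts in the controls is too small to account for it, as the median log2 change of the 72 others was 0.233 in DRRi and 0.01 in pHAN_DRR1.2, against 7.75 and 7.50 for Rpl35. Copies outside the table stay open, as does any step tied to the place of the controls, which were the second condition of both tables, and an effect of the DRR RNA on Rpl35 was not tested.

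The p53 response list was higher in DRRi than in GFPi, which received RNAi as well. Less advanced differentiation stays open. In pHAN_DRR1.2, where contractile genes were higher, the list lay at percentile 95.4 and not at the low end. That library comes from a separate experiment in which all 35 cell cycle genes also lay above 0. It therefore cannot stand for the reverse of DRRi. A response to double-stranded RNA cannot be told apart from the rest: 0 of 11 interferon response genes were 1.5-fold or more higher, but the list lay above the central 95% of random lists under 2 of 7 settings. Other targets of the RNAi reagents also stay open, since 0 of the 16 p53 genes higher in DRRi were 1.5-fold or more lower in pHAN_DRR1.2, and a single RNAi library gives no second reagent to compare. Loss of the DRR RNA and differences in culture or library preparation between DRRi and GFPi were not tested.

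More genes went the same way in DRRi and pHAN_DRR1.2 than independent lists would give, 40 against 6.70. At 1.5-fold and a mean of 1 FPKM or more, opposite genes exceeded that count to a like degree, 34 against 6.04. The independent count takes genes as equally likely to pass, and unequal variability of genes was not tested. Several coding sequences or an overlapping locus were no more common among the 40 genes, at 25% (exact 95% interval 12.7 to 41.2), than among all genes tested (25.8%). Values were already summed over the coding sequences of a gene, and the interval is wide. A part played by overlapping loci thus stays open. Noise of genes near the lower limit of the filter is argued against for same-way genes. With a mean of 5 FPKM or more their count was 7.82 times that of independent lists. Opposite genes came to 3.53 times the independent count there. At 2-fold the ratios were 39.6 for 10 opposite genes and 11.2 for 3 same-way genes. The excesses were thus alike at some settings only. A difference shared by both GFP controls, or by both DRR libraries, stays open and is confounded with the groups.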
